A study of Homo sapiens with 4 samples.

How the data were processed

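Total RNA was extracted with the RNeasy kit and made into libraries with the SMARTER mRNA-seq kit, per the labels. There were 4 libraries, 1 for each combination of line (HCT116 or A549) and treatment (2 µM YHM18 for 48 h, or normal medium). Counts per gene were deposited by the authors as whole numbers, per the file headers. FPKM per gene were deposited by the authors in the same table, per the file headers, and relative to the counts they differed between libraries by a nearly constant factor. The aligner, the counting tool, their versions, the gene lengths and whether counts are of reads or fragments are not given in the sources used here. The submitters' processing notes name only the mouse builds GRCm38 and mm10. The table holds 35275 human gene identifiers and 0 mouse ones. Of these, 34195 are in GENCODE release 29 for the human build GRCh38, all on the same chromosome and 26763 (78.3%) with the identical start, so coordinates are given on GRCh38. Columns for another cell line, 4 in number, match no sample of the series and were not used.

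Library totals were 55448354, 54572281, 54024558 and 55935922 counts for HCT116 control, HCT116 treated, A549 control and A549 treated. The median gene at FPKM 1 or more had 1638 to 1915 counts, so counting error was small beside the changes described. Gene type and shared exon bases were taken from GENCODE release 29. A gene with 50% or more of its exon bases inside other genes was treated as uncertain.

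Changes per line are differences of log2(FPKM + 1), treated minus control, among genes at FPKM 1 or more in at least 1 of the line's libraries. A change of 1 or more was counted as 2-fold, with no p-value, since there is 1 library per group. Folds of single genes are ratios of FPKM computed from counts with an exact 95% binomial interval. Against 0 counts the fold is a lower bound on a floor of 3 counts of 1 library. The effect common to both lines was tested on counts with edgeR 4.0.16 (quasi-likelihood, TMM factors 1.10, 1.03, 0.954 and 0.929), with cell line and treatment as terms and 1 residual degree of freedom, at a Benjamini-Hochberg adjusted p of 0.05. The plan named limma on log2(FPKM + 1) unless the table held raw counts, in which case edgeR was to be used. The common biological coefficient of variation was 0.268 and the prior degrees of freedom 4.37. limma 3.58.1 and DESeq2 1.42.0 (2229 genes without an adjusted p) were run with the same terms under R 4.3.3. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

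The groups, tests, 39 gene lists, alternative settings and rule for naming genes were fixed before the data were examined. A list is summarised per line by the median change of its measured members and its percentile among 10000 random lists of the same size drawn within 20 bins of mean expression, and a list outside the middle 95% of these is said to lie outside the random range. For the common effect, each list's p-values were also adjusted over the list alone. That count for the mesenchymal and extracellular matrix list is not reported here. The 39 lists cover the cell cycle, p53 and DNA repair, stress and metabolic responses, signalling pathways, immune responses, adhesion and matrix, drug metabolism, epigenetic regulators, markers of the lines and markers of other cell types. The genes named are protein-coding. Per line they are the 12 with the largest increase and the 12 with the largest decrease. For both lines they are the 12 in each direction with the largest smaller change, and for the difference the 6 on each side. Also named are the line markers and up to 4 members of each list whose mean change over both lines was largest in absolute value. MT-CO1, the kallikreins other than KLK5 and KLK7, the keratins beside KRT85, FCGBP, the genes of partners and the KEGG pathway genes lie outside the rule and were chosen after their values were seen. The overlap of the lines is set beside the product of the list sizes divided by the genes measured in both.

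Alternatives were a pseudocount of 0.1 or 5 FPKM, no filter or a filter at FPKM 5, scaling to the same sum of FPKM, centring on the median gene, protein-coding genes alone, a log2 threshold of 1.5, and for the common test no cell line term, robust moderation, limma with and without a trend, and DESeq2. Scaling without mitochondrial genes, leaving out genes that share exons, DESeq2 size factors in edgeR, leaving out mitochondrial genes and total scaling for the lists were added after seeing the data. Leaving out a library would leave no residual degree of freedom, so no such test was made. The common test was tested on simulated data with 200 changed genes of 14371 in 3 runs: it recovered 28.7% of 2-fold and 80.7% of 4-fold changes with a mean of 3.7 false calls. The simulated changes were the same in both lines, and the spread of each gene followed the trend over expression alone. These rates therefore need not hold for the real data, where the lines can respond differently. The list percentile was tested on simulated data for HCT116 alone, with 200 lists of 20 genes. There 4.5% of lists with no change fell outside the 95% range, and 99.0% of lists shifted by 0.5 lay above it. These rates need not hold for A549, where changes spread more widely (standard deviation 0.645 against 0.4 in HCT116). Nor need they hold for lists whose genes change together.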

Results

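RNA sequencing compared 2 human cancer cell lines treated with YHM18, a pyrimidine derivative given in the labels by its code name, with cells of the same line in normal medium. HCT116 is a colorectal cancer line and A549 is a non-small cell lung cancer line. Cells were exposed to 2 µM for 48 h, and 1 library was measured for each of the 4 combinations of line and treatment. The libraries held 55448354 (HCT116 control), 54572281 (HCT116 treated), 54024558 (A549 control) and 55935922 (A549 treated) counts, and 11689 to 12402 genes reached 1 FPKM. Nothing in the labels says how many cultures went into a library, so intervals and floors below cover counting error and not the difference between cultures.

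The libraries carried some genes known to mark each line, more clearly for A549 than for HCT116. Of 20 A549 line markers, 16 were measured in A549 and 7 in HCT116. Of 15 HCT116 line markers, 4 were measured in HCT116 and 5 in A549, so that list as a whole did not tell the lines apart. ALDH1A1, an aldehyde dehydrogenase, stood at FPKM 2714 and 3040 in the control and treated A549 libraries and at 0.086 and 2.67 in the HCT116 libraries. AKR1B10, an aldo-keto reductase, stood at 1610 and 1269 in A549 and at 0.21 and 0.81 in HCT116. The intermediate filament gene VIM stood at 201 and 199 in A549 and at 5.43 and 4.16 in HCT116. CDKN2A, a cell cycle inhibitor, stood at 4.76 and 3.98 in HCT116 and at 0.042 and 0.19 in A549. CDX2, an intestinal transcription factor, stood at 2.85 and 3.06 in HCT116 and at 0.075 and 0.21 in A549. As a list, the A549 line markers had a median log2 change of 0.15 over 7 measured members in HCT116 and 0.25 over 16 in A549, and the HCT116 line markers 0.095 over 4 and 0.44 over 5. All 12 genes at FPKM 100 or more in both A549 libraries and under 1 in the HCT116 control were higher in the treated HCT116 library, by a median of 0.117% of their A549 level, and 24 of 33 were higher when the minimum was lowered to FPKM 25 and the limit of 1 was set on the mean of both HCT116 libraries. The HCT116 values of ALDH1A1, ALDH3A1, AKR1C2, AKR1B10 and KRT81 carry that limit.

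Transcripts of the mitochondrial genome took a larger share of the treated library in both lines, 12.7% against 8.27% of counts in HCT116 and 15.2% against 9.37% in A549. All 13 mitochondrial mRNAs were higher in the treated library, with a median log2 change of 0.57 (0.18 to 1.08) in HCT116 and 0.61 (0.14 to 0.79) in A549. MT-CO1, a subunit of cytochrome c oxidase, went from 1.49% to 2.77% of counts in HCT116 and from 2.77% to 4.84% in A549. The nuclear oxidative phosphorylation genes were lower instead, with medians of -0.27 in HCT116 (below the random range, the middle 95% of random lists matched on expression) and -0.29 in A549 (within it). COX8A stood at FPKM 180 in the control and 110 in the treated HCT116 library and at 189 and 142 in A549.

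Targets of p53, the tumour suppressor that halts the cycle of damaged cells, stood higher in the treated library in both lines. CDKN1A, the p21 inhibitor of cyclin-dependent kinases on chromosome 6 (36676460 to 36687337, GRCh38), was 4.10-fold higher in HCT116 (95% counting interval 4.004 to 4.206, FPKM 40.3 to 165) and 3.81-fold higher in A549 (3.72 to 3.90, FPKM 46.8 to 178). GDF15, a stress-induced secreted cytokine, was 6.95-fold higher in HCT116 (6.66 to 7.26) and 2.52-fold higher in A549 (2.40 to 2.65). TP53INP1, BTG2 and ZMAT3, which act in p53-dependent arrest and death, were 4.44-fold, 3.60-fold and 3.37-fold higher in HCT116 and 5.17-fold, 3.85-fold and 4.86-fold higher in A549. The list of p53 target genes had a median log2 change of 0.93 in HCT116, where 12 of 27 measured members were 2-fold higher, and 0.83 in A549, where 11 of 28 were. No member was 2-fold lower in either line. Other genes among the 12 with the largest joint increase were the efflux transporter ABCC3 (FPKM 1.94 to 10.8 in HCT116, 31.6 to 106 in A549), the sulfatase SULF2 (2.35 to 8.94, 7.15 to 25.4), the lysosomal enzyme IDUA (0.97 to 4.84, 1.42 to 5.29) and ASS1 of the urea cycle (12.8 to 32.5, 3.63 to 14.2). ACTA2, smooth muscle actin, went from FPKM 0.93 to 3.99 in HCT116 and from 2.42 to 22.9 in A549, with 30.1% of its exon bases shared with other genes, among them FAS. C19orf71 had 0 counts in both controls and was at least 42.9-fold higher in HCT116 and at least 33.2-fold higher in A549 against a floor of 3 counts of 1 library, with 37.8% of its exon bases shared with MFSD12. AC023055 went from FPKM 0.11 to 10.3 in HCT116 and from 0.064 to 5.98 in A549, but 90.1% of its exon bases lie in other genes, so its value is uncertain.

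Genes of DNA replication and mitosis stood lower in both treated libraries. TK1, the thymidine kinase of S phase, was 3.35-fold lower in HCT116 (3.24 to 3.47, FPKM 119 to 35.5) and 10.2-fold lower in A549 (9.46 to 11.01, FPKM 61.6 to 6.04). CDC20, an activator of the anaphase-promoting complex, was 3.19-fold lower in HCT116 and 11.2-fold lower in A549. CCNA2, cyclin A2, was 3.39-fold and 8.22-fold lower, and BIRC5, survivin, 3.22-fold and 10.7-fold lower. KIF20A, a kinesin of cytokinesis, PBK, a mitotic kinase, NEK2, a centrosome kinase, CDKN3, a phosphatase of cyclin-dependent kinases, and the kinetochore genes SPC25 and NUF2 were lower by log2 changes of -1.61 to -1.66 in HCT116 and -2.16 to -3.41 in A549. APOBEC3B, a cytidine deaminase, went from FPKM 6.80 to 1.49 in HCT116 and from 11.8 to 1.15 in A549, with 23.3% of its exon bases shared. TOMM6 was lower in both lines as well (13.7 to 2.17 and 28.8 to 1.20), but all of its exon bases are shared with other genes, so its value is uncertain.

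As lists, the G2/M and mitosis genes had a median log2 change of -1.40 in HCT116, with 29 of 30 members 2-fold lower, and -2.76 in A549, with 30 of 30. The DNA replication and G1/S genes had medians of -1.03 (18 of 30 members 2-fold lower) and -2.46 (28 of 30), with GINS2 of the replicative helicase at log2 changes of -1.60 and -3.12. The DNA repair genes had medians of -0.90 (6 of 20) and -1.78 (18 of 20), with the nuclease EXO1 at 11.8 to 4.76 and 10.5 to 0.81 and the repair gene BRCA1 at log2 changes of -1.04 and -2.57. The tubulins, the subunits of microtubules, had medians of -0.62 (1 of 11) and -1.42 (10 of 11), with TUBB4B at 252 to 130 and 202 to 34.7 and TUBA1B, which shares 36.6% of its exon bases, at 368 to 158 and 483 to 61.7. The replication-dependent histones stood the other way, with medians of 0.76 over 6 measured members in HCT116 and 0.33 over 9 in A549 and H1-2 at FPKM 3.76 to 7.82 and 9.13 to 14.7. Over the same 9 members the HCT116 median was 0.21. Apart from that last value, which was not set beside random lists, each of these medians lay outside the random range.

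**Figure D1:**
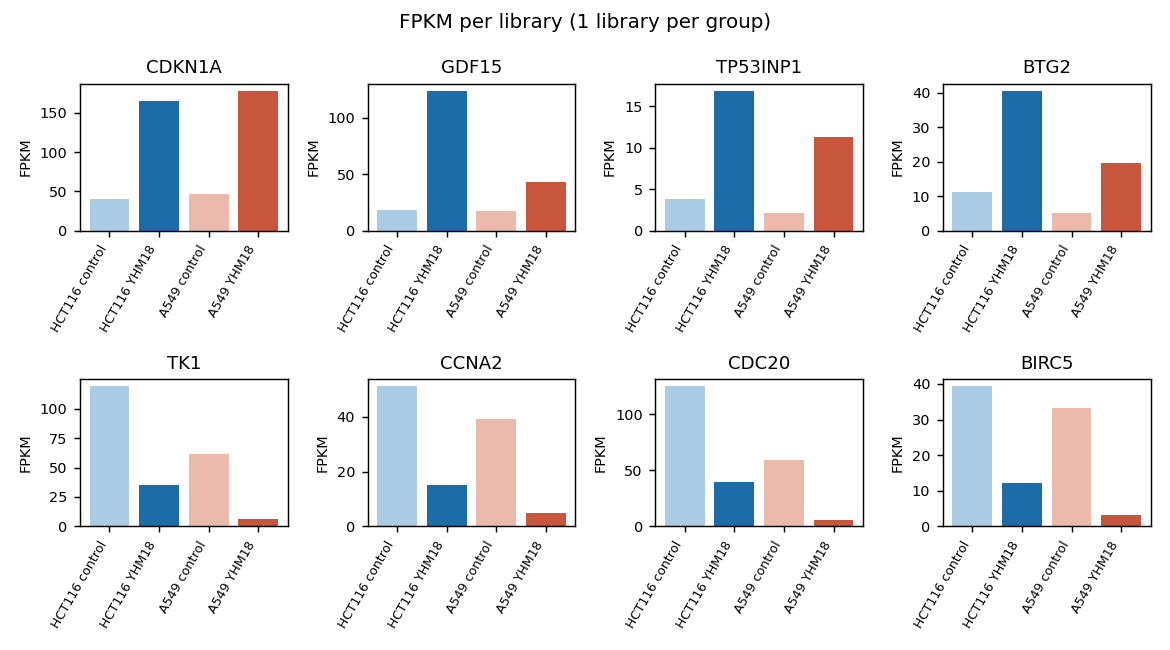
FPKM of 8 genes in each of the 4 libraries. CDKN1A, GDF15, TP53INP1 and BTG2 belong to the p53 targets, and TK1, CCNA2, CDC20 and BIRC5 to the cell cycle genes. Bars start at 0 and there are no error bars, since each group holds 1 library.

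The effect common to both lines was tested with edgeR over 14371 genes, with the cell line as a term and 1 residual degree of freedom. No gene passed over all genes, with 1834 of 14371 at an unadjusted p under 0.05. On the same genes limma called 0 (2097 unadjusted) and DESeq2 called 719 (329 higher, 390 lower, 1979 unadjusted). CDKN1A had a common log2 change of 2.06 (SE 0.20, edgeR adjusted p = 0.236) and TK1 one of -2.46 (SE 0.43, edgeR adjusted p = 0.236). The smallest edgeR adjusted p, 0.0911, was that of AC023055. When adjusted over the list alone, 23 of 29 p53 targets, all higher, 30 of 30 G2/M genes, 29 of 30 G1/S genes, 19 of 20 DNA repair genes and 7 of 11 tubulins, all lower, and 0 of 9 histones passed, against 0 of each list over all genes. With protein-coding genes alone, 7 genes passed in edgeR: CDKN1A, TP53INP1, MT-CO1, FCGBP and AC023055 higher, and KRT85 and Z83844 lower. KRT85 had 0 counts in both HCT116 libraries, so its call rests on A549 alone, and Z83844 had 21 counts in the control and 0 in the treated A549 library, so its call rests mainly on HCT116. FCGBP was named after its values were seen.

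In HCT116, 141 of 12867 measured genes were at least 2-fold higher and 260 at least 2-fold lower in the treated library. Beside GDF15, CDKN1A and ABCC3, 2 kallikrein genes on chromosome 19, whose products are secreted proteases, stood at the higher end: KLK7 was 4.59-fold higher (4.33 to 4.88, FPKM 37.7 in the treated library) and KLK5 8.34-fold higher (6.59 to 10.7, FPKM 0.72 to 6.05). The neighbouring KLK6 (13.1 to 47.3), KLK10 (2.13 to 8.53) and KLK8 (6.16 to 12.8) were higher as well and were chosen after their values were seen. PCDH7, a protocadherin, was 6.74-fold lower (6.24 to 7.30, FPKM 6.29 to 0.93). NBPF19, 1 of a family of close paralogs and so uncertain, went from 5.05 to 0.67. The cell cycle genes TK1, CCNA2 and KIF20A completed the part of the lower list that shares few exon bases. The remaining genes named by the rule share 62.3% to 100% of their exon bases with neighbours and are uncertain: RPL36A-HNRNPH2, AC004922, AC023055, AL591806, BOLA2, FAM47E-STBD1 and RTEL1-TNFRSF6B on the higher side, and AC138811, Z83844, SENP3-EIF4A1, TOMM6, TVP23C-CDRT4, AC131160 and AL445685 on the lower side. RPL36A-HNRNPH2 went from FPKM 0.42 to 31.1 while its parts RPL36A (52.0 to 58.6) and HNRNPH2 (47.5 to 41.4) differed little.

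Among metabolic and stress lists in HCT116, cholesterol synthesis genes were lower with a median of -0.43, and all 22 members were below 0. EBP, a sterol isomerase, stood at FPKM 19.1 in the control and 7.75 in the treated library, INSIG1, which restrains sterol synthesis, at 8.62 and 2.75, and SQLE, squalene epoxidase, at 18.6 and 9.87. Heat shock proteins were lower (-0.54, HSP90AA1 835 to 498), as were endoplasmic reticulum chaperones (-0.14), fatty acid synthesis genes (-0.24) and glycolysis genes (-0.24, PGAM1 186 to 112), the last 3 within the random range. The NRF2 targets had a median of 0.27, with NQO1, a quinone reductase, at 178 and 443 and AKR1C2 under the limit given above. The ATF4 and amino acid response genes had one of 0.32, with 3 of 22 members 2-fold higher. The aryl hydrocarbon receptor targets had a median of 0.73 over 5 of 11 members and of 0.20 over the 8 measured in either line. The 5 included TIPARP (14.1 to 24.1) and NQO1, which is also on the NRF2 list. The ERK pathway output genes had a median of 0.21, with the phosphatases DUSP4 (15.7 to 37.2) and DUSP6 (58.7 to 114, 40.5% of exon bases shared). The YAP and TEAD targets had a median of 0.19, with NT5E at 17.1 and 33.6. The ribosomal proteins (0.099), the epithelial adhesion genes (0.13, ITGB4 42.2 to 81.9) and the ferroptosis regulators (0.16, SAT1 209 to 445) stood above the random range as well, but their medians were -0.10, -0.042 and -0.036 when each library was scaled to the same sum of FPKM. That scaling moved the median of all genes by -0.16 as well, and the 3 lists stayed above the random range under it. The type I interferon genes had a median of -0.36 over 11 measured members, with 5 above and 6 below 0. Over the 16 measured in either line it was -0.063. Apart from the endoplasmic reticulum chaperones, fatty acid synthesis and glycolysis, the HCT116 medians here over members measured in HCT116 lay outside the random range. Those over members measured in either line were not set beside random lists.

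In A549, 457 of 12663 measured genes were at least 2-fold higher and 836 at least 2-fold lower. The cell cycle genes filled the lower end: beside TK1, CDC20 and PBK, UBE2C, a ubiquitin-conjugating enzyme of mitosis, was 11.7-fold lower (10.6 to 12.9, FPKM 55.7 to 4.75), and MKI67, the proliferation marker Ki-67, 10.99-fold lower (10.6 to 11.4, FPKM 39.7 to 3.61). CCNB1, cyclin B1, and GINS2 had log2 changes of -3.15 and -3.12, and FPKM went from 44.0 to 3.95 for ZWINT of the kinetochore, from 23.1 to 1.78 for RRM2 of ribonucleotide reductase and from 28.5 to 2.48 for SPAG5 of the spindle. KRT85, a hair keratin, went from 3323 counts (FPKM 19.4) to 0, at least 1190-fold lower against a floor of 3 counts of 1 library. Its close paralogs KRT81 (1429 to 781), KRT86 (21.7 to 11.3) and KRT83 (10.3 to 4.66) were lower by less, so the KRT85 value is uncertain.

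At the higher end in A549, PIP, prolactin-induced protein, was 13.2-fold higher (10.7 to 16.6, FPKM 2.46 to 32.6), and LCN2, the iron-siderophore carrier lipocalin 2, 10.9-fold higher (9.45 to 12.7, FPKM 1.98 to 21.9). ANGPTL4, an inhibitor of lipoprotein lipase, was 9.04-fold higher (8.16 to 10.0, FPKM 2.60 to 23.6) and CP, the copper protein ceruloplasmin, 7.57-fold higher (7.11 to 8.07, FPKM 2.46 to 18.7). NDRG1, a stress-induced gene, went from FPKM 5.19 to 33.3, the hormone STC1 from 2.13 to 13.6 and the adhesion molecule CEACAM7 from 0.66 to 6.57. UGT1A3, AC023055, AL928654 and STX16-NPEPL1 share 73.9% to 90.1% of their exon bases with other genes and are uncertain.

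**Figure D2:**
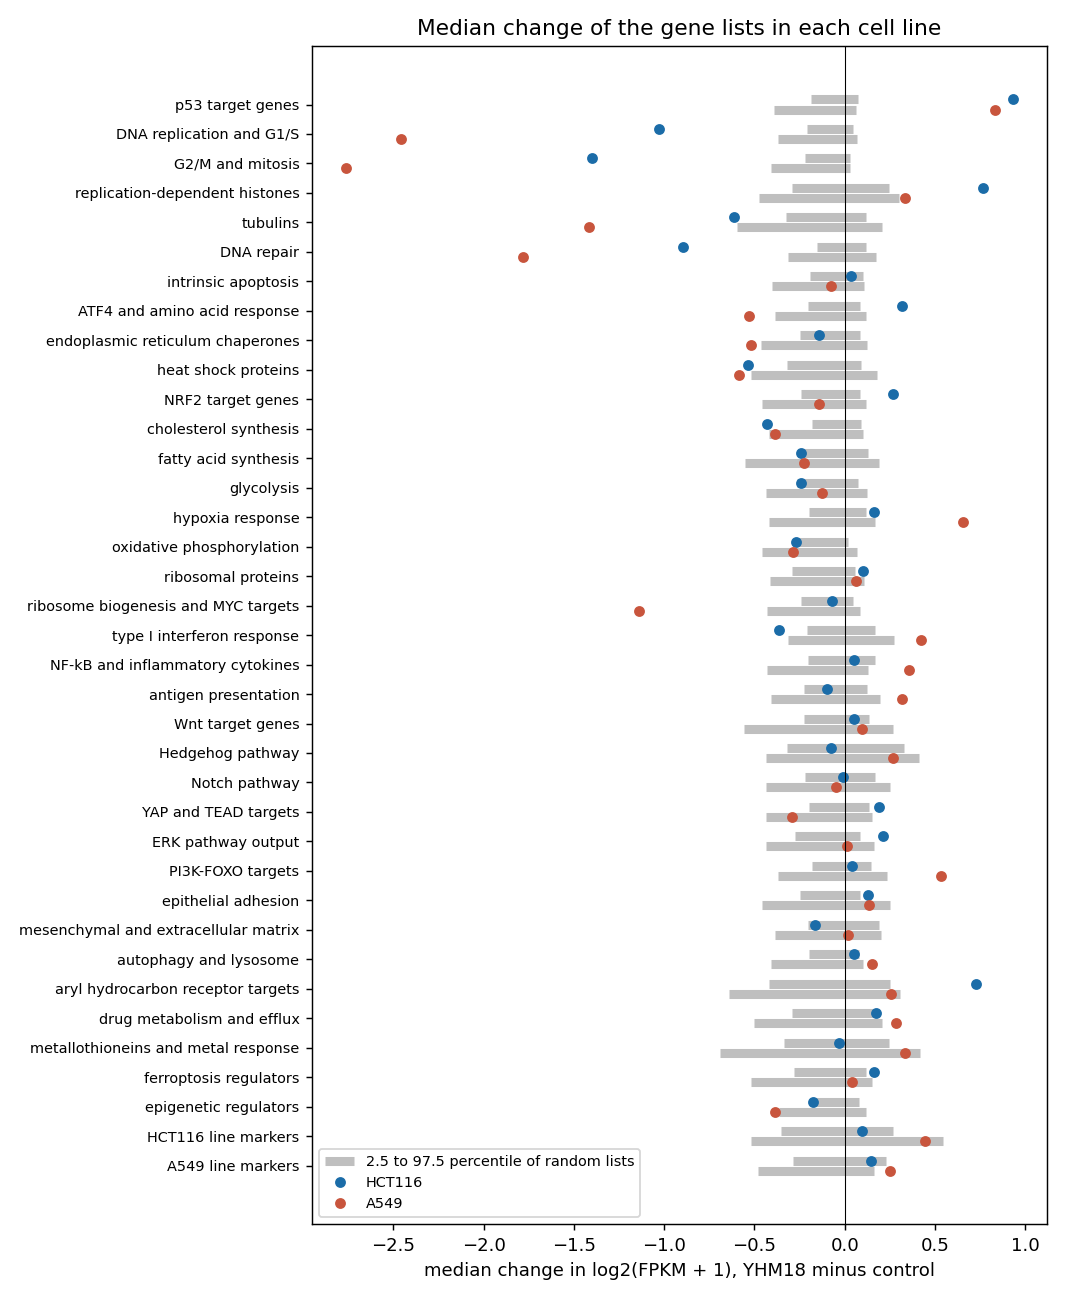
Median change in log2(FPKM + 1), treated minus control, of the 37 gene lists measured in both lines, with the range that holds the middle 95% of random lists of the same size matched on mean expression in grey. Ribosomal proteins, epithelial adhesion genes and ferroptosis regulators in HCT116 fall below 0 when libraries are scaled to the same sum of FPKM, which lowers genes as a whole, and stay above the random range.

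The hypoxia response list in A549 had a median of 0.65, with 6 of 18 measured members 2-fold higher, among them ANGPTL4, NDRG1 and CA9, a carbonic anhydrase (0.73 to 5.86). In HCT116 the median was 0.16 with 1 of 18 2-fold higher. The ribosome biogenesis and MYC target genes had a median of -1.14 in A549, with 16 of 25 2-fold lower, such as ODC1 of polyamine synthesis (76.3 to 22.8), MRTO4 (23.2 to 6.92) and NCL, nucleolin (142 to 56.8). In HCT116 that median was -0.073. The ATF4 and amino acid response genes had a median of -0.53 in A549, with 6 of 25 members 2-fold lower and 1 higher. The serine synthesis gene PSAT1 stood at 143 in the control and 42.0 in the treated library. Heat shock proteins (-0.59, HSP90AA1 504 to 144), endoplasmic reticulum chaperones (-0.52, PDIA4 82.8 to 45.7) and epigenetic regulators (-0.39, the DNA methyltransferase DNMT1 13.2 to 2.70) were lower. Epigenetic regulators had a median of -0.17 in HCT116. The PI3K-FOXO targets had a median of 0.53 (TXNIP 1.18 to 5.99), the NF-kB and inflammatory cytokine genes 0.36 (the chemokine CXCL8 13.9 to 40.2), the antigen presentation genes 0.32 (HLA-E 20.2 to 44.2) and the autophagy and lysosome genes 0.15 (GABARAPL1 6.64 to 19.8), against 0.042, 0.053, -0.10 and 0.049 in HCT116. The drug metabolism and efflux genes had a median of 0.28 in A549 (EPHX1 85.9 to 196) and 0.17 in HCT116. The type I interferon genes had a median of 0.42 in A549 (IFIT2 0.74 to 3.37, but OAS3 13.4 to 3.23), which was -0.093 with genes under FPKM 5 left out. Apart from that last value, which lay within the random range, these A549 medians lay outside it. Of the HCT116 medians set beside them, only that of the hypoxia list lay outside it.

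The other lists lay within the random range, except the immune cell markers and, in A549, the A549 line markers. The intrinsic apoptosis genes had medians of 0.033 in HCT116 and -0.076 in A549, although its p53-driven members BBC3 (2.92 to 6.42 and 3.38 to 12.6) and BAX (13.4 to 25.7 and 26.2 to 42.2) were higher in both. Medians in HCT116 and A549 were 0.050 and 0.095 for Wnt targets, -0.074 and 0.27 for the Hedgehog pathway, -0.009 and -0.048 for the Notch pathway, -0.17 and 0.017 for mesenchymal and extracellular matrix genes, -0.033 and 0.33 for metallothioneins, and -0.24 and -0.23 for fatty acid synthesis. In A549 they were -0.15 for NRF2 targets, -0.38 for cholesterol synthesis, -0.12 for glycolysis, -0.29 for YAP and TEAD targets, 0.013 for ERK pathway output, 0.26 for aryl hydrocarbon receptor targets, 0.038 for ferroptosis regulators, 0.135 for epithelial adhesion and 0.062 for ribosomal proteins. Ribosomal protein genes took 5.04% and 5.42% of counts in the HCT116 libraries and 4.31% and 4.91% in A549. Immune cell markers reached 3 measured members, in A549 alone, with a median of 0.62 and CD14 at FPKM 1.30 and 2.54. Of the fibroblast and endothelial markers, ACTA2 and COL1A1 were tested. Adjusted over the list alone in edgeR, ABCC3 passed in the NRF2 list, ABCC3 and ALDH3A1 in the drug metabolism list, SAT1 in the ferroptosis list and ACTA2 in the fibroblast list, all higher, and EBP in the cholesterol list and OAS3 in the interferon list, both lower. In each of the other lists except the mesenchymal and extracellular matrix genes 0 genes passed when adjusted over the list alone, and over all genes 0 passed in every list. Some medians outside the random range came inside it under another setting: histones in A549 (pseudocount of 0.1, FPKM 5 minimum, total scaling), hypoxia in HCT116 and immune markers in A549 (pseudocount of 5), YAP and TEAD targets in HCT116 and epigenetic regulators in A549 (FPKM 5 minimum), and drug metabolism and A549 line markers in A549 (total scaling). In HCT116, 2 lists moved outside it: Wnt targets (median 0.40 at the FPKM 5 minimum) and epigenetic regulators (-0.21 with a pseudocount of 0.1, -0.25 at the FPKM 5 minimum, -0.36 with total scaling). Over the members measured in either line, HCT116 medians were 0.10 for YAP and TEAD targets, 0.072 for drug metabolism, 0.007 for mesenchymal genes and 0.075 for HCT116 line markers, and A549 medians 0.16 for aryl hydrocarbon receptor targets, 0.051 for epithelial adhesion, 0.0 for Wnt targets and 0.19 for HCT116 line markers. Mean and median had opposite signs for mesenchymal genes in HCT116 and for apoptosis, glycolysis, Wnt, Notch, ERK output and ferroptosis genes in A549. The median common log2 change in edgeR was opposite in sign to a line's own median for the ATF4 and interferon lists in HCT116 (-0.044 and 0.17), for NRF2 and YAP targets in A549 (0.19 and 0.17), for antigen presentation, Hedgehog, mesenchymal and metallothionein genes in HCT116 (0.26, 0.14, 0.15 and 0.31), for apoptosis genes in A549 (0.10), and for glycolysis and Notch genes in both lines (0.008 and 0.15).

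Of the genes 2-fold lower in HCT116 and measured in both lines, 84.6% were 2-fold lower in A549 as well. The reverse did not hold, since 611 genes were 2-fold lower in A549 only. Of 11159 genes measured in both lines, 193 were 2-fold lower in both, where independent lists of 228 and 804 would share 16.4, and 28 were 2-fold higher in both, where lists of 81 and 286 would share 2.08. The 28 became 84 with a pseudocount of 0.1 FPKM, 9 with one of 5 FPKM, 16 at the FPKM 5 minimum, 18 with libraries scaled to the same sum, 42 with centring and 7 at a log2 threshold of 1.5. Under the same settings, in that order, the 193 became 280, 70, 166, 280, 160 and 22. Of the 193, 53 belonged to the cell cycle or DNA repair lists, of whose genes 80 were measured, and 7 of the 28 were p53 targets, of which 26 were measured. A further 10 genes were 2-fold changed in opposite directions, where 11.7 would be so by chance. Over 14371 genes, which are not independent replicates, the log2 changes of the lines had a Pearson correlation of 0.488 and a Spearman correlation of 0.447.

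**Figure D3:**
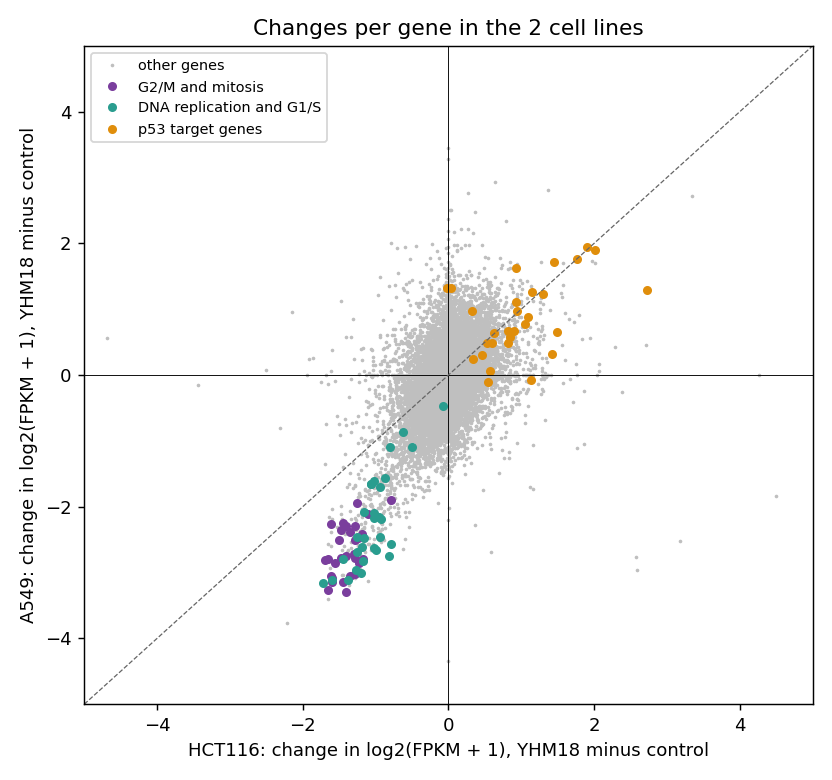
Change in log2(FPKM + 1), treated minus control, of each gene in HCT116 (horizontal) and A549 (vertical), with the G2/M and mitosis genes, the DNA replication and G1/S genes and the p53 targets in colour. The dashed line marks equal changes in both lines.

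The changes of 952 genes differed by 1 or more on the log2 scale between the lines, 406 with the A549 change above that of HCT116 and 546 with it below. With each line centred on its median gene the balance turned round, to 532 above and 461 below. All 60 genes of the G1/S and G2/M lists were lower relative to control in A549 than in HCT116, 45 of them by 1 or more, with a median difference of -1.28. For the p53 targets the median difference was -0.10. Of the genes with the largest differences, PIP was at 0 in both HCT116 libraries and KRT85 likewise. AC138811, UGT1A3, Z83844, TVP23C-CDRT4, AC005020, RPL36A-HNRNPH2, AL591806, BOLA2, AC004922 and HNRNPUL2-BSCL2 share 80.0% to 100% of their exon bases with other genes and are uncertain. The design has no residual degree of freedom for a test of the difference between the lines.

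The balance of higher and lower genes depended on scaling, threshold and pseudocount. Of the 2-fold changed genes, 35.2% in HCT116 and 35.3% in A549 were higher, against 21.3% and 22.8% with libraries scaled to the same sum of FPKM, 51.6% in A549 with each line centred on its median gene and 45.0% in A549 with scaling on counts outside the mitochondrial genome. At a log2 threshold of 1.5 it was 49.4% in HCT116 and 19.6% in A549, with a pseudocount of 5 FPKM 31.2% and 20.8%, and with one of 0.1 FPKM 44.4% and 44.3%. Scaling to the same sum moved the median change of all genes by -0.16 in HCT116 and -0.12 in A549, and centring moved it by 0.13 in A549. Counts also depended on the value added before taking logs: with 0.1 in place of 1 FPKM, 832 genes in HCT116 and 2280 in A549 were 2-fold changed, and with 5 FPKM 112 and 438.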

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

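The tests on p53 targets, on the mitochondrial share beside the hypoxia genes, on glycolysis genes and on A549-abundant genes in HCT116 were chosen only after the results were seen, as was scaling without mitochondrial genes as a setting. The median change of the ATF4 and amino acid response genes was above the random range in HCT116 and below it in A549, a gap (A549 minus HCT116) of -0.847, and the difference was not tested. Over the same 25 members the medians were 0.234 in HCT116 and -0.531 in A549. That of the type I interferon genes was below the range in HCT116 and above it in A549, a gap of 0.786, and the difference was not tested. Over the same 16 members the median difference was 0.464, with medians of -0.063 in HCT116 and 0.367 in A549, and the A549 median was -0.093 with a minimum of FPKM 5. AL591806 (-5.707), BOLA2 (-5.556) and RPL36A-HNRNPH2 (-6.327), given as the A549 minus the HCT116 log2 change, were higher in the treated HCT116 and lower in the treated A549 library, and the difference was not tested. Each shares more than 90% of its exon bases with other genes.

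Cell cycle genes were lower in treated A549 than in treated HCT116 relative to control. Scaling by mitochondrial transcripts is argued against by its size. Rescaling on counts outside the mitochondrial genome moved the median of all genes by 0.058 in HCT116 and 0.075 in A549. Shifts so alike nearly cancel between the lines. The median difference over 60 genes, -1.276 before and after rescaling, could therefore not have moved far. A weaker response of p53 targets in HCT116 is argued against as well, since the median A549 change minus the HCT116 change over 29 p53 targets was -0.105. HCT116 cells that went on cycling beside arrested ones cannot be told apart from cells that each lowered these genes: the log2 ratios in HCT116 had an interquartile range of 0.424 around -1.31, 40.2% of control, against 0.685 around -2.98, 12.6% of control, in A549, and both cases allow a narrow range. A difference between the lines in their response, which the design names, was not tested and stays open.

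Hypoxia genes were higher in treated A549, with a median of 0.654, and little so in HCT116. Scaling by mitochondrial transcripts is argued against, since the mitochondrial share of counts was higher by 5.83 percentage points in the treated A549 library, which lowers the values of other genes. The state at harvest of the cells behind the single treated A549 library, such as density or spent medium, cannot be told apart from the compound. Glycolysis genes, which would be higher if oxygen ran short, had a median of -0.124, but a partial response would leave this open. An effect of the compound in A549 stays open too and was not tested separately.

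A set of 12 genes abundant in A549 was higher in the treated than in the control HCT116 library, while the A549 line marker list had 4 of 7 measured members above 0 there. Reads carried over from the A549 libraries may be a cause, since 100.0% of the 12 genes, chosen at FPKM 100 or more in A549 and under 1 in the HCT116 control, were higher in the treated library, by a median of 0.117% of their A549 level (quartiles 0.0652% to 0.168%). With the mean of both HCT116 libraries under 1 it was 9 of 9, and with that rule and a minimum of FPKM 25 together it was 24 of 33, and for HCT116 genes in treated A549 12 of 20. The excess of ALDH1A1 was 0.67 times the median of the other 11 genes, so it did not stand out on that scale. The scale divides by the A549 level and so presumes carry-over. ALDH1A1 went from 16 to 486 counts in HCT116, and a response of its own is not excluded. Over the 12 genes the excess ranged from 0.0225% (CPLX2) to 0.2758% (AKR1C2) of the A549 level, so it was not 1 common share. AKR1B10, AKR1C2 and AKR1C3 are also on the NRF2 list, which had a median of 0.268 in HCT116. Only AKR1C3 of these reached FPKM 1 there. A joint response of the 12 genes to the compound was not tested and stays open.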

How the results depend on the processing

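Scaling without mitochondrial genes, leaving out genes that share 50% of their exon bases, DESeq2 size factors in edgeR, leaving out mitochondrial genes and total scaling for the lists were chosen after seeing the data. Where values moved the cause was not tested, except that a higher threshold or pseudocount lowers a count of 2-fold changes by construction. With a pseudocount of 0.1 FPKM, 832 genes in HCT116 and 2280 in A549 were 2-fold changed, 364 in both in the same direction, the correlation was 0.372 and 2194 genes differed between the lines. With a pseudocount of 5 FPKM these were 112, 438, 79, 0.564 and 183. With a threshold of 1.5 on the log2 scale, 77 and 418 genes passed and 29 in both. The correlation was 0.436 with no filter, 0.564 with a filter at FPKM 5 (where 619 genes differed between the lines), 0.517 with total scaling, 0.472 with median scaling, 0.538 with protein-coding genes only and 0.529 without genes that share exon bases. The other counts stayed within 1.5 times the reported ones, at 288 to 483 genes in HCT116, 932 to 1424 in A549, 182 to 298 in both and 698 to 993 differing.

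For the common effect, edgeR called 3 genes with total scaling (KRT85, with 0 counts in HCT116, and Z83844 lower, AC023055 higher), 1 with median scaling and 1 with DESeq2 size factors in edgeR (AC023055 in each), and 7 with protein-coding genes only. limma with a pseudocount of 5 FPKM called 6 genes, all of the mitochondrial genome and higher, and DESeq2 called 719. The count was 0 with no filter, with a filter at FPKM 5, with robust moderation, without mitochondrial genes, and with limma at a pseudocount of 1 FPKM, of 0.1 FPKM or without a trend. With no replicate block, that is without the cell line term, it was 0, with 213 at an unadjusted p under 0.05. Leaving out any library left no residual degree of freedom and gave no test. Among gene lists, 353 of 370 alternative medians were counted as unchanged, 9 came inside the random range and 4 moved outside it. Medians near 0 within the range, which total scaling can turn, were not counted as changes of sign. A change of sign was counted for 4 medians that lay outside the range at first. These were type I interferon in A549 with a filter at FPKM 5 (-0.093, which also came inside it), and ribosomal proteins (-0.101), epithelial adhesion (-0.042) and ferroptosis regulators (-0.036) in HCT116 with total scaling. The last 3 stayed above the random range, and total scaling lowers the median of all genes by construction. None of 1736 alternative values for the 217 named genes was counted as a change of sign. A pseudocount cannot change a sign, and a filter or a choice of genes leaves a gene's value as it was. Only the settings that rescale the libraries could therefore show a change of sign. Changes near 0, such as that of VIM in A549, are smaller than the shift from centring, so their direction is not settled by this count. Depth limited genes near 1 FPKM and genes with 0 counts, for which only bounds were given.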

Other observations

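The pathways and gene sets in this part were chosen only after their values were seen, over 279 KEGG pathways in each line. In A549, genes of complement and coagulation had a median log2 change of 0.66 (0.30 in HCT116), with complement C3 at FPKM 23.3 in the control and 60.9 in the treated library, CFB at 1.75 and 9.80 and CFD at 16.8 and 66.6. ECM-receptor interaction genes had a median of 0.57 in A549, with COL4A5, a basement membrane collagen, at 8.26 and 27.6. The median was 0.34 in HCT116. Proteasome genes were lower in both lines, with medians of -0.36 in HCT116 and -0.67 in A549, and PSMC3 of the regulatory particle stood at FPKM 61.5 and 35.7 in HCT116 and at 55.6 and 20.9 in A549. Spliceosome genes had medians of -0.27 in HCT116 and -0.67 in A549.

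Of 73 protein-coding genes at FPKM 3 or more that differed 10-fold within a line, 19 (26.0%) share 50% or more of their exon bases with other genes, against 2.98% of 9545 genes at FPKM 3 or more. At 20-fold it was 16 of 19 genes (84.2%). In HCT116 all 9 such genes at either threshold share exons, and in A549 13 of 67 at 10-fold and 10 of 13 at 20-fold do. The 20-fold threshold was used first by a slip, in place of the 10-fold one set down before it, so both are given.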
